A study of Mus musculus and Mus musculus x Mus spretus with 8 samples.

How the data were processed

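Single cells described in the labels as glomus cells of the mouse carotid body, the oxygen-sensing organ at the fork of the carotid artery, were profiled by RNA sequencing. The labels give 8 cells from wild-type pups at postnatal days 4 to 5, of which 7 carry the strain label C57BL/6 and 1, cell 2, the label C57BL/6 X SPRET/EiJ, a cross with a strain of another mouse species. Per the labels' protocols, each cell was lysed, its RNA was reverse transcribed and amplified by PCR, and the cDNA was made into a library with a transposase kit. The reads were aligned with Bowtie to the mouse build mm10, per the submitters' processing notes. The Bowtie version, the read counter, the gene annotation, the handling of reads that match several places and the strand setting are not given in the sources used here. No molecular identifiers are mentioned in the labels, so reads copied from the same molecule cannot be told apart.

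For each cell the authors deposited 2 values for each of 24060 gene symbols. The first is a read count, per the file headers a raw count, and its total differs from cell to cell. The second is RPM, a read count scaled by sequencing depth, per the file headers. In every cell the deposited RPM equalled the count divided by the sum of counts in that cell and scaled to the same total in all cells, so it corrects for depth and for nothing else, neither transcript length nor the yield of the reverse transcription. The table holds no mitochondrially encoded genes, and 25 symbols had been turned into dates; these were left as they were and enter no gene list.

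The labels name no animal or litter for any cell. The strain labels require more than 1 animal. The spread between cells can thus include differences between animals, strains and, by the sex genes below, sexes. The 8 cells therefore count as 1 sample, and no p-value, standard error or count of changed genes was computed from cells. Values are given per cell, or as the median, range and SD over the 8 cells, which describe these cells alone. The unit of all levels is the deposited RPM, and log2 levels are log2(RPM + 1). This scale understates differences that involve genes near 0. A gene was called detected in a cell at 1 RPM or more. A count of 0 reads allows a level of up to 3 reads, which is 0.0993 RPM in the deepest cell and 0.758 RPM in the shallowest. This limit covers counting error only, since PCR copies are not independent molecules and a transcript may be lost before amplification.

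Choices made before the data were examined were the comparisons, 22 pairs of related genes, 41 gene lists with markers of other cell types among them, and the rule for the genes named in the text. By that rule the text may name both genes of every pair, the 3 selection genes, the 4 members of each list with the highest mean log2 level among those detected in at least 6 cells (or the single highest member of a list with none), the 20 highest genes of the table outside the ribosomal protein list and mitochondrial genes, the 20 on-off genes with the highest lowest level in the cells that detect them, and all genes of the sex list. Some genes that the rule takes, and 1 of the pairs, are not reported here, though they remain members of their lists. Other genes are named only with a statement that they were chosen after their values were seen. Symbols were matched as written. One listed member, in the list of chloride, HCN, ASIC and further channels, was not among the symbols.

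Related genes were compared within each cell as the difference of their log2 levels. The level of a list is the mean over its members and cells, placed among 10000 random lists of the same size drawn from the table; most genes of the table were detected in no cell, so a high percentile states only that the list is expressed above the typical symbol. The variability of a list is the median over its members of the SD of log2 level over the 8 cells, set against 10000 random lists of detected genes matched on mean level in 20 bins. The text gives it for lists under the 1st or above the 99th percentile, a limit set after the values were seen; a figure shows all lists with at least 3 detected members. On-off genes are those at 30 RPM or more in each of 2 to 6 cells and under 1 RPM in all others. For every cell in turn, genes detected in at least 4 cells were counted when the cell lay outside the range of the other 7 by more than 2 log2 units. Spearman correlations between cells were taken over genes detected in at least 1 cell; they are across genes, which are not independent replicates. A cell was said to stand apart in a value when its gap to the nearest other cell, divided by the range of the 8 values, passed the 95% limit of Dixon's test. Named genes detected in no cell were left out of this step after some had been seen to stand apart on a single read.

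Gene positions came from the GENCODE M21 annotation of the same build, by symbol. The longest transcript of each of 307 genes was searched with blastn 2.17.0 against all annotated transcripts of other genes that do not overlap it, and the percent of its length inside matches of at least 95% identity and at least 50 bases was recorded. Statistics used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9. The pairs, list levels, list variability, on-off genes, counts outside the range, cells standing apart and the split by copies were tested on simulated data. For the pairs, 200 planted differences of 4 log2 units were recovered with a median of 3.96. For the on-off genes 200 of 200 planted genes were called, and for the counts outside the range of the other cells 195 of 200. The planted on-off genes lay far above the limit or near 0 and varied by counting noise alone. Genes planted outside the range varied less between cells than many real genes. No loss of transcripts was simulated and false on-off calls were not counted, so these rates may not hold in real cells. A planted list of 60 genes with low spread lay at percentile 0, while none of 100 random lists passed the limits. Among 2000 groups of 8 normal values, 5.45% held a value called apart.

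Alternatives fixed beforehand were another pseudocount, other detection limits, a rescaling of cells to one median, leaving out each cell, another set of genes for the correlations, random lists from detected genes only, and other limits for on-off genes and for genes outside the range. With random lists from detected genes only, each list was also cut to its members detected in at least 1 cell. Added after the data were seen were the thinning of reads in the hybrid cell or in all cells and, already among the cells left out in turn, the values without cell 4, which stands apart in many genes.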

Results

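The data describe 8 single cells, picked from the carotid body and selected for expression of Th, Uchl1 and Kcnk3. Glomus cells sense oxygen, carbon dioxide and pH in arterial blood and signal to the nerve that drives breathing. The labels name 1 group, so the questions are what these cells express, which of several related genes they use, and how alike they are. The counts summed to 3960200, 30218206, 5310906, 4943206, 4474679, 7074346, 6487518 and 6891690 reads in cells 1 to 8. The deepest of them is cell 2, the C57BL/6 X SPRET/EiJ cell.

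The cells detected 6956, 5604, 5243, 5140, 4040, 4242, 6257 and 6699 genes, a median of 5424 with an SD of 1072. Of 10768 genes detected in any cell, 1173 were detected in all 8 and 2005 in 1 cell only. The number did not follow depth, as the shallowest cell detected the most genes. The Spearman correlation between 2 cells had a median of 0.391 over the 28 pairs and a range of 0.275 to 0.459. Cell 4 had the lowest median correlation to the others, 0.318, against 0.378 to 0.423 in the remaining cells. Without cell 4 the number of genes detected in all cells was 1402. At a detection limit of 10 RPM it was 676 over all 8 cells.

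All 3 selection genes were present in all 8 cells, which checks the labels and is no finding. Th, the rate-limiting enzyme of catecholamine synthesis (chromosome 7, 142892752 to 142931128, minus strand of mm10), had a median of 2078 RPM and a range of 764 to 3785. Uchl1, a ubiquitin hydrolase of neurons and neuroendocrine cells (chromosome 5, 66676091 to 66687234), had a median of 1318 RPM and a range of 331 to 2201, with the lowest value in the hybrid cell. Kcnk3, a background potassium channel that is closed by acid (chromosome 5, 30588170 to 30625271), had a median of 1384 RPM and a range of 199 to 2212.

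Gnas, which encodes the stimulatory G protein alpha subunit, was the highest gene in 7 of the 8 cells. Its median was 17545 RPM and it took up to 3.00% of a cell's reads. In cell 4 the highest gene was Tubb5 at 9429 RPM. Also among the highest 20 genes were Epas1, with a median of 8521 RPM, Rgs4 with 7510, Ndufa4l2 with 5976 and Eml5 with 2280. Others were Th, Cyb561, Ddc, Itm2b, Grina, Nedd4, Snap25, Slc39a6, Gnb2l1, Chgb, Maged1, Nrep, Slc25a4 and Tcf4, with medians from 1312 RPM for Tcf4 to 2619 RPM for Itm2b. Among these, cell 4 lay below all other cells by the widest margins in Ndufa4l2 (2.23 RPM), Epas1 (170 RPM), Maged1 (182 RPM), Itm2b (222 RPM) and Chgb (153 RPM).

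**Figure D1:**
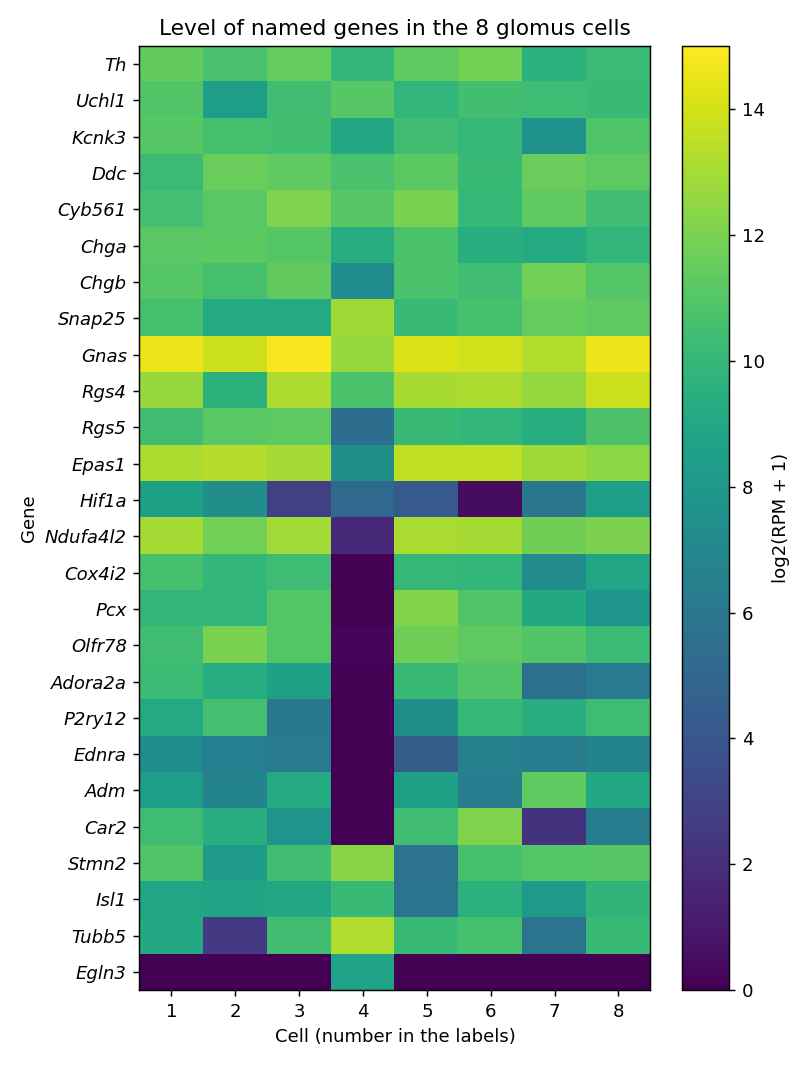
Level of 26 named genes (vertical axis) in each of the 8 cells (horizontal axis), coloured by log2(RPM + 1) from 0 to 15. Th, Uchl1, Kcnk3 and Gnas are present in all cells, while Cox4i2, Pcx, Adora2a, P2ry12, Ednra, Adm and Car2 have 0 reads in cell 4 and Egln3 has reads in cell 4 alone.

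Genes of catecholamine synthesis and storage were expressed in these cells, with 8 of 17 list members detected in at least 6 cells. Ddc, which makes dopamine, had a median of 2407 RPM and Cyb561, an electron carrier of the granule membrane, 2257 RPM, both in 8 of 8 cells. Gch1, which makes the cofactor of Th, had a median of 506 RPM. Slc18a2, the vesicular monoamine transporter of neurons, was detected in 7 cells at a median of 850 RPM and had 0 reads in cell 7. Its relative Slc18a1 was detected in 5 cells, and within cells Slc18a1 lay below Slc18a2 in 7 of 8, by a median of -3.82 log2 units (SD 4.65, and -5.03 to -2.61 with 1 cell left out). Dbh, which turns dopamine into noradrenaline and was named after its values were seen, was detected in cell 4 at 2588 RPM and in cell 8 at 33.2 RPM, and had 0 reads in the other 6 cells.

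Genes of dense-core granules and of regulated release were also present. Of 15 secretory granule genes 10 were detected in at least 6 cells, led by Chgb (median 1879 RPM), Chga (1322), Scg5 (741) and Cpe (539). Of 25 vesicle release genes 18 were, led by Snap25 (1607), Syt1 (1122), Cplx1 (991) and Vamp2 (273 to 857 RPM), all in 8 of 8 cells. Of 18 sympathoadrenal genes 7 were, with Rgs4 highest and the transcription factors Phox2a (502) and Isl1 (476) in 8 of 8 cells. The mean level of each of these lists and of the catecholamine genes lay at percentile 100 of random lists. That of the 3 selection genes did too, which is no finding, since the cells were selected for them. Chgb stood at 153 RPM in cell 4 against 1325 or more in the others, and Snap25 at 7293 RPM in cell 4 against at most 2859.

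Among genes of the hypoxia-inducible factor (HIF) pathway, Epas1, which encodes the HIF-2 alpha subunit (chromosome 17, 86753700 to 86833410), far exceeded Hif1a, which encodes HIF-1 alpha. Epas1 was higher in all 8 cells, by a median of 6.39 log2 units (SD 3.58, range 2.29 to 13.06), and the medians were 8521 and 47.8 RPM. The smallest difference was in cell 4. Arnt2 exceeded its relative Arnt, both partners of the HIF alpha subunits, in 6 cells and lay below it in 2, by a median of 4.85 log2 units (SD 5.52), and by 2.56 to 7.14 with 1 cell left out (7.14 without cell 2, 3, 4 or 6 and 2.56 without cell 1, 5, 7 or 8). The prolyl hydroxylase genes that mark HIF for degradation were lower, with medians of 24.0 RPM for Egln1 and 34.2 RPM for Egln2. Egln1 and Egln2 each led in 4 cells, and the median difference of -0.31 log2 units (SD 4.29) was 1.17 without cell 4, 5, 6 or 8 and -1.79 without cell 1, 2, 3 or 7. Egln3 was detected only in cell 4, at 411 RPM, and Egln3 minus Egln1 had a median of -2.09 (SD 4.28). In all, 5 of 12 pathway genes were detected in at least 6 cells and the list lay at percentile 99.9, or 91.3 among random lists of detected genes. Of 26 HIF target genes 10 were detected in at least 6 cells, at percentile 99.96, led by Pfkp (466 RPM), Ldha (315 RPM), Aldoa (258 RPM) and Adm (343 RPM, 0 reads in cell 4). The glucose transporter gene Slc2a3 exceeded Slc2a1 in all 8 cells, by 6.69 log2 units at the median (Slc2a1 minus Slc2a3 was -6.69, SD 3.17, and -8.29 to -5.09 with 1 cell left out). Ldha exceeded Ldhb in all 8 cells by 7.44 (SD 2.03), but 76.8% of the Ldhb transcript and 55.0% of the Ldha transcript have near-identical copies elsewhere, so this difference is uncertain.

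Ndufa4l2 and Cox4i2, mitochondrial genes associated with low oxygen in other tissues, were abundant. Ndufa4l2 (chromosome 10, 127514967 to 127517154) had a median of 5976 RPM against 30.2 RPM for Ndufa4, and was higher in 7 of 8 cells, by a median of 7.71 log2 units (SD 3.93, or 0.758 without cell 4). Cox4i2 (chromosome 2, 152754173 to 152765037) had a median of 979 RPM against 731 for Cox4i1, the subunit present in most tissues, a median difference of 0.10 log2 units (SD 3.49), or 0.19 (SD 1.10) without cell 4. Pcx, which encodes pyruvate carboxylase, had a median of 959 RPM. The 3 genes were at or above 147 RPM for Cox4i2, 3393 RPM for Ndufa4l2 and 233 RPM for Pcx in the 7 cells other than cell 4, where Cox4i2 and Pcx had 0 reads, which allows up to 0.607 RPM, and Ndufa4l2 had 2.23 RPM. Isoforms typical of muscle were low. Cox8b minus Cox8a had a median of -6.35 (SD 1.79), Cox7a1 minus Cox7a2 -5.97 (SD 1.81) and Cox6a2 minus Cox6a1 -7.13 (SD 1.11), negative in all 8 cells. Cox7a1 and Cox6a2 had 0 reads and Cox8b was detected in cell 1 only, so these differences are limits set by the pseudocount, and with 0.1 in place of 1 the first 2 were -9.65 and -9.27. Higd1c and Higd1a were detected in 2 and 3 cells, with a median difference of -0.10 (SD 1.60). This pair is uncertain, because a read-through symbol named after its values were seen, Mettl7a2Higd1c, reached 787 to 2406 RPM in 7 cells and 0 in cell 4, and reads of Higd1c may be counted there. The list of atypical mitochondrial genes lay at percentile 98.6, with 3 of 10 members in at least 6 cells.

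The respiratory complexes were broadly detected. In at least 6 cells the data held 31 of 36 complex I genes, led by Ndufs8 (165 RPM), Ndufv2 (147), Ndufb9 (99.8) and Ndufb5 (74.9). For complex II this was 4 of 4, namely Sdhc (314), Sdha (305), Sdhb (59.8) and Sdhd (38.0). For complex III it was 8 of 10, led by Uqcrfs1 (418), Uqcrc1 (259), Cyc1 (204) and Uqcrq (87.8). For complex IV it was 10 of 12, with Cox4i1, Cox6a1 (140), Cox8a (86.7) and Cox7a2 (66.0) highest, and for complex V 11 of 15, led by Atp5b (831), Atp5a1 (504), Atp5g3 (425) and Atp5d (248). The lists lay at percentiles 100, 99.9, 99.99, 100 and 100 in that order. Levels of some subunits are uncertain because their transcripts have near-identical copies, for example 50.9% of Cox5b, a gene named after its values were seen, at a median of 0.755 RPM.

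**Figure D2:**
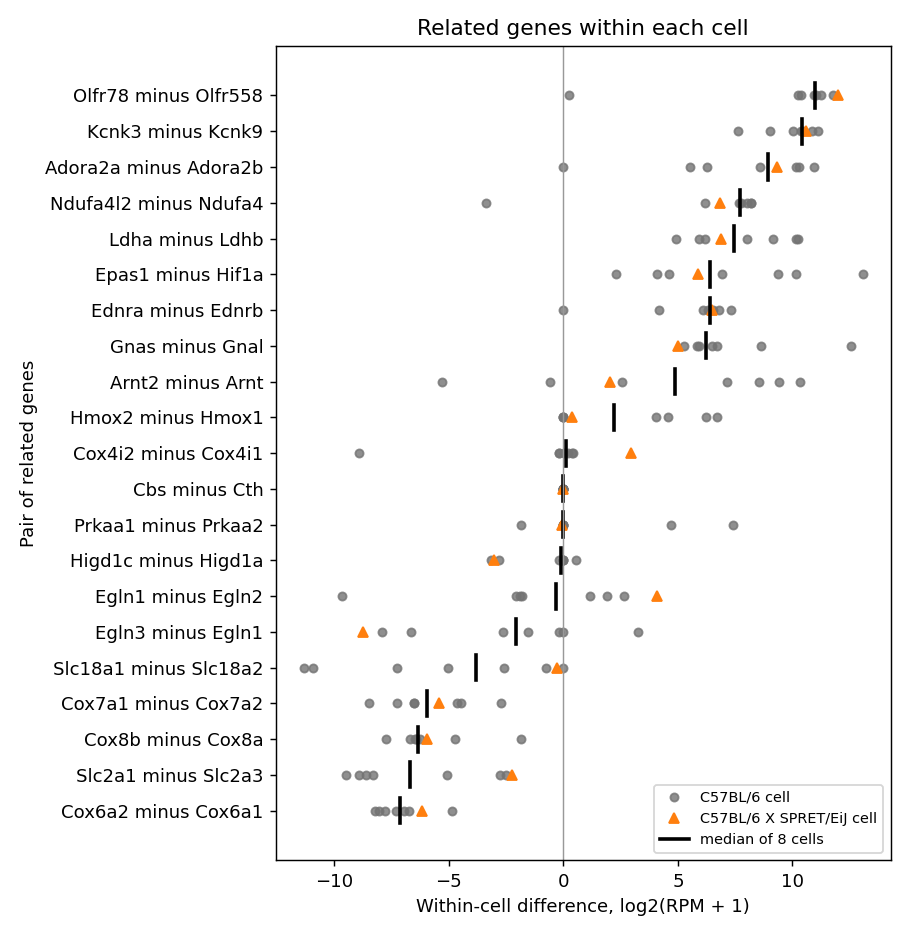
Within-cell difference in log2(RPM + 1) (horizontal axis) for 21 pairs of related genes (vertical axis), with grey circles for the 7 C57BL/6 cells, orange triangles for the C57BL/6 X SPRET/EiJ cell and black bars for the median of 8 cells. Epas1 minus Hif1a and Gnas minus Gnal lie above 0 in all 8 cells, as does Kcnk3 minus Kcnk9, for whose first gene the cells were selected, and the lone low circles of Ndufa4l2, Cox4i2 and Olfr78 are cell 4.

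Of 1102 olfactory receptor genes in the table, 1 was detected in at least 6 cells. This was Olfr78 (chromosome 7, 102738511 to 102759471, minus strand), at a median of 2001 RPM and at 1203 to 4118 RPM in 7 cells, with 1 read (0.202 RPM) in cell 4. Olfr558 had 0 reads in all 8 cells, and Olfr78 minus Olfr558 had a median of 10.97 log2 units (SD 3.87, or 0.659 without cell 4). Another 5 olfactory receptors were detected in 1 to 5 cells and 1096 in none, and the list lay at percentile 0. Of 315 other G protein-coupled receptor genes 11 were detected in at least 6 cells, with the list at percentile 0. The highest were Lphn1 (450 RPM), the purinergic receptor gene P2ry12 (624 RPM), the adenosine receptor gene Adora2a (506 RPM) and the PACAP receptor gene Adcyap1r1 (489 RPM). Adora2a exceeded Adora2b in 7 cells by a median of 8.94 (SD 3.64), and the endothelin receptor gene Ednra exceeded Ednrb in 7 cells by 6.39 (SD 2.39), or 9.69 with a pseudocount of 0.1. Adora2b and Ednrb were detected in no cell. In cell 4 Adora2a, Ednra and P2ry12 had 0 reads.

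Among genes of signalling below these receptors, Gnas had the highest transcript level, followed by Rgs4. Of 34 G protein subunit genes 17 were detected in at least 6 cells, among them Gnb1 (888 RPM), Gnb2 (636 RPM) and Gng2 (474 RPM), and the list lay at percentile 100. Gnas exceeded Gnal in all 8 cells by a median of 6.22 log2 units (SD 2.48). Of 36 cAMP and cGMP genes 8 were detected in at least 6 cells, at percentile 99.7 or, among random lists of detected genes, 83.3, with Prkar1a (828 RPM), Prkacb (585 RPM), Adcy1 (540 RPM) and Pde1b (449 RPM) highest. Among 21 regulators of G protein signalling only Rgs4 and Rgs5 (1232 RPM) were detected in at least 6 cells, with the list at percentile 81.0. Rgs5 stood at 42.5 RPM in cell 4.

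Of 92 potassium channel genes 6 were detected in at least 6 cells and 61 in none, with the list at percentile 0.57. Kcnk3 exceeded Kcnk9, the other acid-sensitive channel gene it can assemble with, in all 8 cells by a median of 10.43 log2 units (SD 1.15), and Kcnk9 had 0 reads in every cell. The cells were selected for Kcnk3, so the direction of this pair was set beforehand and is no finding. Kcnc4 had a median of 108 RPM and was detected in 6 cells. Of 26 calcium channel genes 6 were detected in at least 6 cells, led by Cacna2d1 (320 RPM), the N-type channel gene Cacna1b (227 RPM) and the L-type channel genes Cacna1d (193 RPM) and Cacna1c (70.4 RPM), at percentile 95.4, or 50.1 among random lists of detected genes. Of 13 sodium channel genes Scn8a (222 RPM) and Scn3a (118 RPM) passed in 7 cells each, at percentile 55.7. Of 22 TRP channel genes 1, Trpm7 (247 RPM), was detected in at least 6 cells, at percentile 8.31. Of 18 genes measured in a list of chloride, HCN, ASIC and further channels, only the lysosomal channel gene Tmem175 (47.7 RPM) and the sodium leak channel gene Nalcn (26.5 RPM), neither of them of the 3 named families, were, at percentile 48.4, or 16.9 among detected genes.

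Enzymes proposed to make gaseous messengers were low or not detectable at this depth. Cbs and Cth had 0 reads in all 8 cells, as did Hmox1, and Hmox2 was detected in 4 cells at a median of 7.84 RPM. Hmox2 minus Hmox1 had a median of 2.21 log2 units (SD 2.95), which was 0.38 without cell 3, 4, 7 or 8 and 4.03 without cell 1, 2, 5 or 6. These enzymes stand on a list of 15 gas messenger and redox genes, which lay at percentile 73.4. The 3 list members detected in at least 6 cells were redox genes, Sod2 (223 RPM), Sod1 (71.4 RPM, uncertain because 72.5% of its transcript has near-identical copies) and Por (44.3 RPM). Of 9 AMPK genes none was detected in 6 cells. Stk11 was in 5 and Prkaa1 in 4, Prkaa1 minus Prkaa2 had a median of 0.00 (SD 3.10), and the list lay at percentile 83.1, or 18.2 among detected genes. Of 35 purinergic, cholinergic, GABA and serotonin genes 4 were detected in at least 6 cells, at percentile 13.0, among them the nicotinic receptor genes Chrna3 (540 RPM, 8 of 8 cells) and Chrnb2 (35.8 RPM) and the esterase gene Ache (42.1 RPM). Of 26 neuropeptides and growth factors Npy (167 RPM) and Gal (182 RPM) were, at percentile 15.6. Of 19 acid-base genes 3 were, the carbonic anhydrase genes Car2 (445 RPM) and Car12 (178 RPM) and the sodium-proton exchanger gene Slc9a2 (242 RPM), at percentile 66.4, or 28.9 among detected genes. In cell 4 Car2 and Slc9a2 had 0 reads and Car12 0.202 RPM.

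Ribosomal protein genes were led by Rpl8 (1010 RPM) and included Rpl4 (407 RPM) and Rps3 (249 RPM), and 21 of 83 were detected in at least 6 cells. The list lay at percentile 98.5 among all genes but at 0.01 among detected genes. Of 12 reference genes 8 were detected in at least 6 cells, with Ywhaz (1081 RPM), Tubb5 (1120 RPM), Actb (447 RPM) and Tuba1a (236 RPM) highest and the list at percentile 100. Gapdh and Ppia, named after their values were seen, were below 1 RPM in every cell. Near-identical copies cover 88.0% of the Gapdh transcript, 53.7% of the Ppia, 82.2% of the Rpl4 and 75.3% of the Tuba1a transcript, so the levels of these genes are uncertain.

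Lists differed in how much their genes varied between cells. Genes of complexes I, III, IV and V and the ribosomal proteins varied less than other genes of like mean level. Their median SD was 1.65, 1.27, 1.11, 0.89 and 1.04 log2 units, or -1.44, -1.15, -1.74, -1.23 and -1.10 relative to matched random lists, under the 1st percentile in all 5. With a pseudocount of 0.1 the relative values of complex III and the ribosomal proteins were -1.76 and -1.98. The ribosomal protein genes mostly lay near 0, with 0.529 RPM as the median of the members' medians. Their low spread cannot be told apart from an even residue of reads near 0. Above the 99th percentile were the neuropeptides and growth factors (0.81), the sex genes (0.80), the regulators of G protein signalling (0.78) and the atypical mitochondrial genes (0.94), and these values depended on single cells to different degrees. The neuropeptides were at 0.38 without cell 1, the regulators at 0.49 without cell 4 and the atypical mitochondrial genes at -0.30 without cell 4 and 2.44 without cell 1. The sex genes were at 0.84 to 1.21 with any 1 cell left out, the highest without cell 2.

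**Figure D3:**
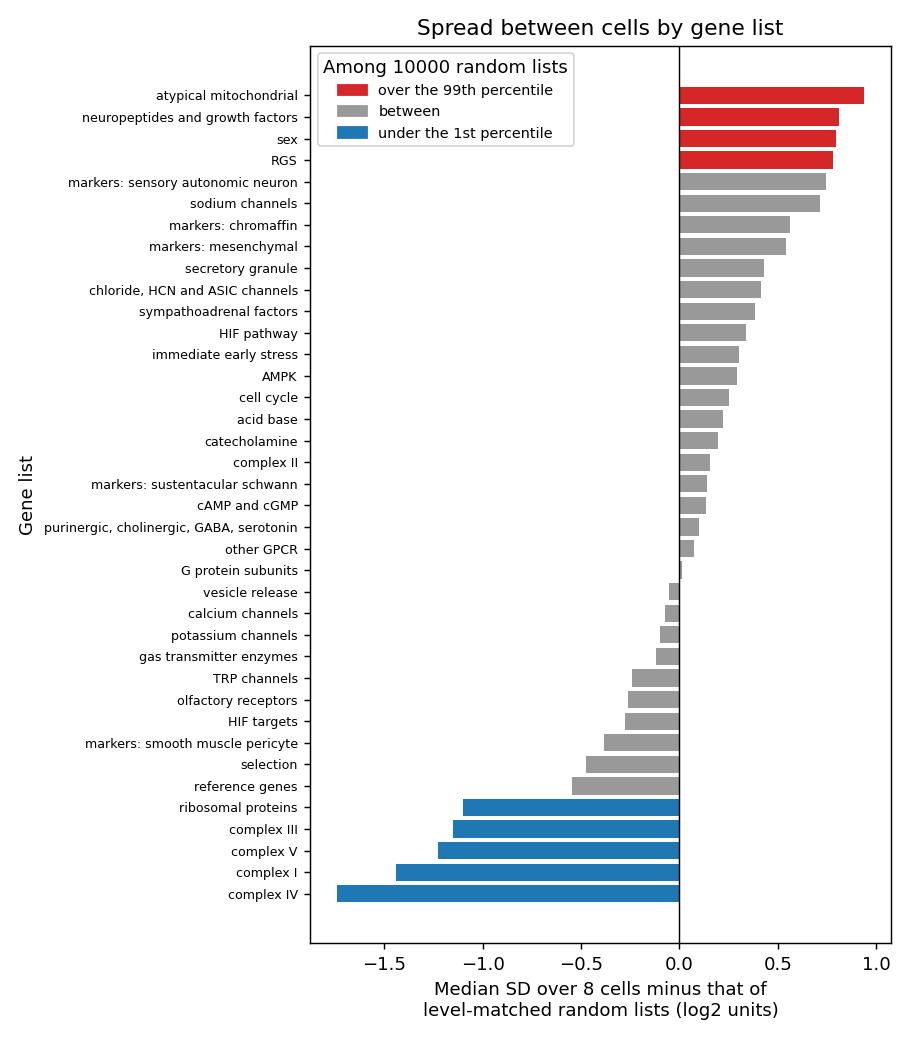
Median SD of log2 level over the 8 cells for the members of each gene list (vertical axis), minus that of random lists matched on mean level (horizontal axis, log2 units). Blue bars are lists under the 1st percentile of 10000 random lists, red bars lists above the 99th; complex IV reaches -1.74 and the atypical mitochondrial genes 0.94.

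Many genes were detected at a high level in some cells and not detected in others. On-off genes numbered 1266, or 273 at a limit of 100 RPM, and 1260 without cell 4. The cells carried from 335 (cell 5) to 794 (cell 1) of them at 30 RPM or more. These counts largely followed the genes detected. Cells 1, 8 and 7 had 794, 743 and 727 of them and detected 6956, 6699 and 6257 genes. Cells 5 and 6 had 335 and 361 and detected 4040 and 4242 genes. A gene that was off therefore cannot be told apart from one whose transcripts were lost before amplification. The highest lowest levels in detecting cells were those of Scnn1b, Dgkk and Ranbp10. Scnn1b, an epithelial sodium channel subunit gene, had 784 to 5842 RPM in 4 cells and at most 0.291 RPM in the others, and Dgkk, a diacylglycerol kinase gene, 769 to 6350 RPM in 6 cells. Others were C1qtnf7, Gfra2, Slco3a1, Ippk, Pard6g, Igsf9, Gipc1, Tmem179, Arf3, Magt1, Rnf144a, Tes, Atad2b, Gsr, Pcdh17 and Ogfod1. Egr1, an immediate early gene, was on in 6 cells at up to 4916 RPM. Of 20 immediate early and stress genes 9 were detected in at least 6 cells, at percentile 100. Fos had 6103, 2801, 208, 7.08, 2399, 1158, 0 and 1160 RPM in cells 1 to 8, while Dusp1 had a median of 371 RPM and the chaperone gene Hspa5 655 RPM in 8 of 8 cells. Of 20 cell cycle genes none was detected in 6 cells, Mcm4 was in 2, and the list lay at percentile 0.81.

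Markers of most other cell types were few in number. No erythroid marker and no immune marker was detected in any cell, with Hba-a1 and Ptprc at 0 reads throughout and the lists at percentiles 0.42 and 0.13. Of 12 endothelial markers only Cldn5 was detected in at least 6 cells (477 RPM, percentile 15.5 for the list), and of 10 mesenchymal markers none was, with Pdgfrb in 4 cells and at most 3 markers in a cell, cell 6 (percentile 16.0). Of 12 sustentacular and Schwann markers only Ncam1 (886 RPM), shared with glomus cells, was detected in at least 6 cells (percentile 39.9, or 66.0 among random lists of detected genes), and of 9 smooth muscle and pericyte markers only Rgs5, also shared (percentile 50.5, or 73.9 among detected genes). The percentiles among detected genes rest on the 4 sustentacular and 3 smooth muscle markers detected in any cell, Ncam1 and Rgs5 among them. Of 7 chromaffin markers Chgb, Chga and Npy were (percentile 99.97), which also stand on the lists of granule genes and neuropeptides. Cells 1 to 8 detected 3, 4, 3, 5, 4, 3, 2 and 6 chromaffin markers. Of 15 neuron markers 6 were detected in cell 4 and 2 or 3 in each other cell (percentile 82.8). Stmn2, Isl1 and Nefh were the neuron markers detected in at least 6 cells, with medians of 1761, 476 and 216 RPM, and in cell 4 Stmn2 reached 5111 RPM and Nefh had 0 reads. Of these, Stmn2 and Isl1 had been marked beforehand as shared with glomus cells.

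The sex genes divided the cells. Xist, which is transcribed from the inactive X chromosome of females, was detected in cells 1, 3, 6, 7 and 8 at 200 to 1251 RPM. Y-linked genes were detected in cell 2, with Ddx3y at 356 RPM and Eif2s3y at 39.7 RPM, and in cell 4, with Eif2s3y at 573 RPM and Uty at 2.43 RPM. At the detection limit no cell carried both, and cell 5 carried neither. Tsix had 0 reads in all cells, Kdm5d was below 1 RPM in all, and the list lay at percentile 59.5, or 25.0 among detected genes.

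Cell 2, the C57BL/6 X SPRET/EiJ cell, did not stand out from the C57BL/6 cells by the number of genes in which it differed. Of 5936 genes detected in at least 4 cells, it lay outside the range of the other 7 by more than 2 log2 units in 170, 74 above and 96 below. The same count was 75, 190, 322, 374, 300, 126 and 89 for cells 1, 3, 4, 5, 6, 7 and 8, so the hybrid cell ranked 5 of 8. With its reads thinned to the median depth of the others the count was 170. With 1 such cell no test of strain is possible, and reads of SPRET/EiJ alleles that differ from mm10 may have aligned less well.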

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

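The tests on cell 4 and those on copies within a class of genes were chosen only after their results or values were seen, while the other tests on copies, transcript length and spread were written before the differences they measure were computed, though the near-absence of Gapdh and Ppia and the low spread of the lists were already known. A value was looked at more closely when its gap to the nearest other cell was large against the range of the 8 cells. Of 198 results examined this way 42 stood apart, 21 of them in cell 4. These results overlap and are not independent. Olfr78, Ednra, Cox4i2 and Ndufa4l2, for example, were counted in cell 4 both as genes and in their pairs. Chance alone sets a cell apart in about 1 in 20 groups, more often in values as uneven as single-cell levels, and named genes detected in no cell were left out after some of them had been seen to stand apart on a single read.

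Cell 4 stood far from the other cells in genes of several groups. Its median correlation to the others was 0.318 (nearest other cell 0.378). The mean log2 level of the atypical mitochondrial genes was 0.33 (nearest 2.83), that of the acid-base genes 0.014 (nearest 1.36) and that of the neuron markers 3.31 (nearest 1.95). Within the cell, Cox4i2 minus Cox4i1 was -8.94 log2 units (nearest -0.21), Ndufa4l2 minus Ndufa4 -3.39 (nearest 6.198), Ednra minus Ednrb 0.00 (nearest 4.15) and Olfr78 minus Olfr558 0.27 (nearest 10.23). Cox4i2, Ednra, Adm, Pcx and P2ry12 had 0 reads there, and Olfr78 stood at 0.202 RPM, Ndufa4l2 at 2.23 RPM, Rgs5 at 42.5 RPM, Chgb at 153 RPM, Epas1 at 170 RPM and Itm2b at 222 RPM, each below the other 7 cells. Egln3 at 411 RPM and Uty at 2.43 RPM were above them.

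Of genes at 1000 RPM or more in each of the other 7 cells, 4 (Pkib, Ndufa4l2, Dgkh and Olfr78, of which Pkib and Dgkh were named after their values were seen) were under 10 RPM in cell 4. The count was still 4 with every cell thinned to the depth of the shallowest, but at these levels thinning could hardly change it. Cell 4 had more reads (4943206) than cells 1 and 5 (3960200 and 4474679), which had 0 such genes, and this argues against fewer reads. A lower capture of transcripts could remove genes and stays open, because the bound for this test asked for none in any other cell and cell 2 had 1 (Nnat, also named after its values were seen). Cell 2 is the C57BL/6 X SPRET/EiJ cell, whose reads may have aligned less well, so its loss need not be one of capture. Cells 5 and 6 detected fewer genes (4040 and 4242) than cell 4 (5140) and had 0. At 100 RPM in the others and under 1 RPM in the cell the counts were 24 in cell 4, 19 in cell 5 and 9 in cell 6, and the 5 genes at 1000 RPM or more in cell 4 and under 10 RPM in all others were matched by 5 in cell 6. For RNA of a second cell mixed with that of a glomus cell like the others, the highest share of Cox4i2, Ndufa4l2 and Pcx that cell 4 could hold was 0.413% of the lowest of the other cells. This argues against a mixture only if these transcripts were not lost in capture, which stays open. The 3 genes were also chosen after their loss was seen. Chgb, Itm2b and Rgs5 fell less far, to 153, 222 and 42.5 RPM against at least 1325, 1464 and 672 RPM. A mixture is therefore not settled. A neuron picked in place of a glomus cell is a hypothesis: 6 of 15 neuron markers fixed beforehand were detected in cell 4 and at most 3 in any other cell, with Stmn2 at 5111 RPM, Nefl at 1143 RPM and Isl1 at 1110 RPM. However, these 3 had been marked beforehand as genes that glomus cells also express, though Nefl was below 1 RPM in the other 7 cells. Besides, 3 of the 15 were detected in at least 6 of the 8 cells, and Nefh had 0 reads in cell 4. Cell 4 also detected 5 of 7 chromaffin markers (2 to 4 in 6 cells, 6 in cell 8), but Chga, Chgb, Dbh and Slc18a1 among these had likewise been marked as shared. The markers therefore do not settle which type it resembles, nor do Th (972 RPM), Uchl1 (2201 RPM) and Kcnk3 (521 RPM), for which all cells were selected.

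Reference and ribosomal protein genes such as Gapdh and Ppia were at or near 0. Genes of the ribosomal protein, reference and respiratory complex lists with 50% or more of their transcript in a near-identical copy lay -4.55 log2 units from those with under 10% (63 and 60 genes, median over genes of the mean log2 level), beyond the -1.91 to 1.97 of random splits, but 49 of the former and 4 of the latter were ribosomal. Within the reference and respiratory complex genes the difference was -4.71 (14 and 56 genes, random splits -1.001 to 1.17), so reads shared with copies are a likely source of low values there. Within the ribosomal proteins it was -0.63 (49 genes against the 33 under 50%, random splits -0.74 to 0.60), with 8 and 7 detected in all cells. Only 4 ribosomal protein genes had under 10% in a copy, so most of the 33 carried copies too. This split therefore cannot decide whether copies are the source, and the low ribosomal values stay open. Among genes without copies the shorter 30 lay -0.59 from the longer 30, inside the -0.87 to 0.83 of random splits, which argues against a loss of short transcripts among them, and no biological explanation was tested.

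Respiratory complex and ribosomal protein genes varied little between cells. Matched on transcript length as well as mean level, their median SD was 1.24 log2 units. This lay -0.99 from random lists, which spanned 2.01 to 2.46, against -1.27 with matching on mean level alone. Length was matched only in 4 groups within each level bin, so members may be shorter than the genes they were matched to. Length so matched did not account for the whole gap, but an even amplification of short transcripts stays open. The 48 members with under 10% of their transcript in a copy, most of them respiratory, had a median SD of 1.59, or -1.35 from random lists spanning 2.65 to 3.18, which argues against a uniform floor from shared reads in these. Whether a shared regulation of these genes may hold their levels even is a hypothesis, found and examined on the same 8 cells, and no biological explanation was tested.

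The remaining values that stood apart were these. Cell 2 had 30.2 M reads, against 7.07 M in the next deepest cell. In cell 2, Uchl1 was at 331 RPM (nearest other cell 932), Ndufb9 at 0.761 RPM (nearest 69.5), Ywhaz at 307 RPM (nearest 945) and Ddx3y at 356 RPM (nearest 0). In cell 1, Higd1c was at 14.1 RPM (nearest 2.22), Cox8b at 33.6 RPM (nearest 0.232) and Gnb2 at 2383 RPM (nearest 842). In cell 3, Slc2a1 was at 68.2 RPM (nearest 0.809), Sdha at 3.58 RPM (nearest 122), Cacna2d1 at 2.26 RPM (nearest 161) and Lphn1 at 9.60 RPM (nearest 122.7), and the mean log2 level of the gas messenger and redox genes was 2.48 (nearest 1.75). In cell 5, Isl1 was at 53.6 RPM (nearest 269), Scn8a at 0 RPM (nearest 183), Egln1 minus Egln2 at -9.64 log2 units (nearest -2.06) and the mean log2 level of the sex genes at 0.048 (nearest 1.31). In cell 6, Gch1 was at 1.27 RPM (nearest 87.0) and Scn3a at 0.141 RPM (nearest 59.1). In cell 7, Slc18a2 was at 0 RPM (nearest 164) and Ldhb at 9.40 RPM (nearest 1.74).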

How the results depend on the processing

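The thinning of reads was chosen only after the data were seen; all other alternatives were fixed beforehand. With each result counted once per alternative, those that answer a comparison stayed within their spread (1 SD, or 1.5 times for counts) 1111 times, moved further 68 times, and turned 5 times from a value beyond it. Within their spread some pairs still shifted, with ranges over the cells left out of -1.79 to 1.17 for Egln1 minus Egln2, 2.56 to 7.14 for Arnt2 minus Arnt and 0.38 to 4.03 for Hmox2 minus Hmox1. For single named genes values stayed 1622 times and moved 18 times, all of these under the smaller pseudocount. Leaving out 1 cell cannot shift a mean over these cells by as much as 1 SD. For named and selection genes those checks could therefore only stay, and they are no sign of stability. Pairs, list levels and marker counts also stayed whichever cell was left out. They were judged against the SD between cells, so this too is a weak sign of stability. The rescaling of cells moved no value by more than 0.159 log2 units, and thinning, run only for detection, correlation, on-off genes and the hybrid cell, left these in place. Where a result moved or turned, the cause was not tested. Depth limits what 0 reads can show to levels above 0.0993 to 0.758 RPM.

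At a detection limit of 10 RPM, 676 genes were in all 8 cells and the median number of markers per cell was 1.5 for sustentacular cells and 1 for smooth muscle. Over genes with a mean of at least 10 RPM the median correlation was 0.312. On-off genes at 100 RPM numbered 273. The hybrid cell lay outside the others in 412 genes at a margin of 1 log2 unit and in 41 at 4, and ranked 5 of 8 throughout.

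With a pseudocount of 0.1 the pairs Cox8b, Cox7a1, Cox6a2, Kcnk3, Ldha and Ednra were at -9.65, -9.27, -10.44, 13.76, 10.01 and 9.69 against their partners. List variability relative to random lists was then -1.72, -1.76 and -2.59 for complexes I, III and IV, -1.98 for ribosomal proteins, 1.05 for regulators of G protein signalling, 0.22 for calcium channels, 0.37 for cAMP and cGMP genes, 0.34 for G protein subunits, 1.02 for chromaffin and -1.32 for smooth muscle markers, 0.85 for granule genes and 0.68 for sympathoadrenal genes.

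Among random lists of detected genes the percentiles of list levels were 91.3 for the HIF pathway, 94.86 for HIF targets, 99.99, 99.48 and 99.89 for complexes I, IV and V, 50.12 for calcium channels, 16.9 for chloride, HCN, ASIC and further channels, 16.02 for olfactory and 0.11 for other receptors, 83.31 for cAMP and cGMP genes, 18.19 for AMPK, 28.94 for acid-base genes, 0.01 for ribosomal proteins, 25.0 for sex genes, 65.99 for sustentacular and 73.87 for smooth muscle markers. These percentiles rank only the detected members of each list, for example 6 of 1102 olfactory and 72 of 315 other receptors.

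Leaving out each cell in turn moved the variability of 20 lists. Among lists further from 0 than the SD of random lists, it turned for atypical mitochondrial genes (0.94, range -0.30 to 2.44), granule genes (0.43, range -0.44 to 0.67, and -0.33 without cell 2), sympathoadrenal genes (0.38, range -0.083 to 0.60) and HIF targets (-0.28, range -0.50 to 0.0015), in each case without cell 4 or, for granule genes and HIF targets, cell 2. Lists nearer to 0 also changed sign, among them complex II, TRP and calcium channels, gas messenger and redox genes, vesicle release genes and other receptors. Other ranges were -0.44 to 0.069 for TRP channels, 0.24 to 0.72 for purinergic, cholinergic, GABA and serotonin genes, 0.38 to 0.91 for neuropeptides, -1.19 to 0.10 for gas messenger and redox genes, 0.84 to 1.21 for sex genes, 0.039 to 0.48 for immediate early genes, 0.15 to 0.73 for mesenchymal markers, -1.48 to -1.23 for complex I, -0.42 to 0.27 for complex II, -0.62 to -0.015 for olfactory receptors, 0.49 to 0.86 for regulators of G protein signalling, 0.16 to 0.47 for catecholamine genes, -0.019 to 0.20 for other receptors, 0.025 to 0.77 for chloride, HCN, ASIC and further channels, 0.18 to 0.61 for acid-base genes and 0.20 to 1.02 for chromaffin markers.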

Other observations

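Several genes, all chosen after their values were seen and none of them tested, were high in cell 4 and low in most other cells. Nrp1 and Plxna4, which encode a receptor for semaphorins and its partner, were at 3464 and 3356 RPM in cell 4, while Nrp1 was below 1 RPM in all other cells and Plxna4 reached at most 7.86 RPM. Nefl and Prph, which encode intermediate filament proteins of neurons, were at 1143 and 223 RPM and below 1 RPM elsewhere, while the neurofilament gene Nefh had 0 reads in cell 4 and was detected in 6 other cells. The transcription factor genes Tfap2b (2045 RPM), Hand1 (834 RPM) and Gata2 (279 RPM) were detected in cell 4 alone, and Gata3 was at 661 RPM there and 33.9 RPM in cell 6. Slc6a2, the noradrenaline transporter gene, was at 1873 RPM in cell 4 but also at 1230 RPM in cell 7, 341 RPM in cell 3 and 322 RPM in cell 2.

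Pkib, Nnat and Dgkh were abundant in nearly all cells and stand on none of the lists, so they too were chosen after their values were seen. Pkib, an inhibitor of the cAMP-dependent kinase, had a median of 2265 RPM and at least 1778 RPM in 7 cells, against 0.202 RPM in cell 4. Nnat, an imprinted gene of neural and endocrine cells, had at least 1041 RPM in 7 cells and 0 reads in cell 2. Dgkh, a diacylglycerol kinase gene related to Dgkk, had a median of 1444 RPM and 9.10 RPM in cell 4.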
